A study of Mus musculus with 44 samples.

How the data were processed

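RNA was sequenced from 44 lung samples of C57BL6j mice. Per the labels, each sample came from a lung piece of about 3 mm3 with column-based extraction of RNA. In the subcutaneous model (14 libraries), mice carried LL/2-Luc2 cells, a Lewis lung carcinoma line with a luciferase reporter, under the skin, and the lungs were collected as early metastatic lungs. These mice received the vehicle HBSS (n = 5), recombinant human TIMP2 (rTIMP2) from day 0 (n = 5) or rTIMP2 from day 7 (n = 4). In the intratracheal model (30 libraries), wild-type (WT) mice and mice with a mutant Timp2 gene (MT2) had tumour-free lungs, lungs given tumour cells with HBSS, or lungs given tumour cells with rTIMP2, with n = 5 in each of these 6 groups. The labels give a dose of 200 µg per kg per day by intraperitoneal injection and 1 M (mega) cells per mouse.

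The values are a normalized signal, deposited by the authors as normalized counts, with 1 value per gene and library. Low values step by a constant per library, as an estimated number of reads divided by a size factor would. Between 78.0 and 84.0% of the low values of a library were whole multiples of that step, within a tolerance of 0.02 of a step and up to 20 steps. This share is too low to recover whole reads, so the values were used as deposited and no count model was fitted. Per the submitters' processing notes, Partek, Bowtie2, STAR and DESeq2 were used by the authors with genome build mm10 and the reporter as an extra sequence. The role and order of these tools, their versions, the annotation release, the strand of counting and the treatment of reads that map to several places are not given in the sources used here. Genes that overlap on opposite strands therefore cannot be told apart, and near-identical copies such as Hspa1a and Hspa1b, Prl2c2 and Prl2c3 or Hba-a1 and Hba-a2 have uncertain individual values. The subcutaneous table holds 24150 genes (16705 protein coding) and the intratracheal one holds 26940 (17627 protein coding), where 30 gene names belong to more than 1 gene identifier.

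Groups were taken from the sample titles. The treatment field of the treated intratracheal mice counts upward from Timp2 to Timp11, and the titles, which give WT + T2 or MT2 + T2, were used in its place. The tumour-free lungs also carry the cell-line label, and they were kept as tumour-free because of their titles and a reporter value of 0 in all 10. Replicate numbers count the mice of a group and were not used to pair libraries. The labels do not say how animals were assigned to collection days or to library batches. The tumour-free intratracheal lungs carry sample numbers in another range than the lungs given tumour cells, so a separate cohort or batch cannot be excluded. The p-values measure the spread between these mouse samples, part of which may be technical where the labels do not state separate animals.

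The estimated depth, from the step of each library, was 14.86 to 19.41 M (mega) reads in the subcutaneous libraries (median 16.59) and 10.68 to 17.14 M reads in the intratracheal ones (median 13.28). The 10 most abundant genes took 4.7 to 9.9% of a library. At this depth a value near 1 stands for about 1 read. Genes that reached 10 in fewer samples than the smaller group of a comparison has were not tested. A reporter value of 0 does not exclude a few tumour cells.

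Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust options) on log2 of the value plus 1. Only the groups compared entered a fit, genes needed a value of 10 or more in at least as many samples as the smaller group has, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The 11 comparisons were 3 between the subcutaneous groups, tumour against tumour-free in each genotype, MT2 against WT in tumour-free and in HBSS tumour lungs, rTIMP2 against HBSS in each genotype, and the interactions of genotype with tumour and with rTIMP2. Log2 fold changes are followed by their standard error (SE), and group means by their standard deviation (SD). The reporter Luc2 and the tumour transcript Hmga2 were compared with two-sided exact permutation tests.

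A set of 41 gene lists (627 genes) covered lung and immune cell types, tumour-related programmes and tissues that a lung piece can carry along. Lists with at least 5 tested genes were tested with camera in limma at a preset correlation of 0.01, and again with a correlation estimated per list and with fry. Counts of list members are given over all genes tested and adjusted over the list alone. Camera calls were lost with an estimated correlation in every comparison, so the lists are described mainly by their members.

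The genes named were set by a rule. Timp2 came first in every comparison. Among genes called, with no overlap between the values of the groups and a mean of 50 or more in the higher group, the 10 largest rises and the 10 largest falls were eligible, leaving out numbered gene models, pseudogenes and immunoglobulin and T cell receptor segments. Lists with at least 3 called members gave the 3 with the smallest p in the more frequent direction and up to 2 in the other. Where fewer than 10 genes passed, the 5 with the smallest p were given as values. Interactions used 5 genes each way without the condition on overlap. Members of the lists on metalloproteinases and on suppressive myeloid genes could be given as values whether or not they passed. The groups, the tests, the lists, this rule and the alternative settings, except those stated as chosen later, were fixed before the data were examined. Genes named outside the rule were chosen after their values were seen, which holds for the sex chromosome genes, for Krt13 as a marker of squamous tissue, for Hspa1a and Hspa1b between days 7 and 0 and for members that complete a count of 5 or fewer.

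The alternatives were other pseudocounts, no filter, TMM and median-ratio rescaling, all groups of a table in 1 fit, limma's sample weights, a replicate block and leaving out each library in turn. Another 3 were chosen after seeing the data, which were limma voom on the estimated reads, leaving out 6 libraries high in squamous or skeletal muscle transcripts, and the reporter as a covariate. The same fits were tested on simulated data, described with the sensitivity results. Comparisons that share a group were set against 100 simulations with no effect and against 10 splits of the shared lungs. No column of sample values was left out. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.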

Results

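The series asks how a mutation of Timp2 bears on tumour growth in the lung, and how daily rTIMP2 acts in tumour-bearing mice. TIMP2 is a secreted inhibitor of matrix metalloproteinases. Lung transcripts were compared between 3 treatment groups of a subcutaneous tumour model and 6 groups of an intratracheal model, which crossed genotype (WT or MT2) with tumour-free lungs, tumour with HBSS and tumour with rTIMP2. All groups had n = 5 except rTIMP2 from day 7, which had n = 4. Values are normalized counts.

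Timp2 was abundant in every group. In tumour-free lungs it averaged 10619 ± 519 (SD, n = 5) in WT and 6105 ± 144 in MT2 mice, a log2 fold change of -0.80 ± 0.047 (SE, limma adjusted p = 1.7e-07). In the HBSS tumour lungs Timp2 was lower than in tumour-free lungs of WT mice (6900 ± 838, log2 -0.63 ± 0.11, adjusted p = 0.00036). In MT2 mice it was higher than in tumour-free lungs (8809 ± 2371, log2 0.49 ± 0.18, adjusted p = 0.029), and that call was lost when any of 7 libraries was left out (MT2 HBSS replicates 1, 2 and 3 and MT2 tumour-free replicates 2 to 5), with adjusted p from 0.051 to 0.069. HBSS tumour lungs of the 2 genotypes did not differ in Timp2 past the threshold (log2 0.32 ± 0.21, adjusted p = 0.77). Treatment with rTIMP2 was not followed by a called change of Timp2 in WT (8731 ± 1834, adjusted p = 0.2) or MT2 lungs (7019 ± 1658, adjusted p = 0.66), though Timp2 in WT lungs passed without rTIMP2 replicate 4 (adjusted p = 0.021). In the subcutaneous model Timp2 was 9865 ± 588 with HBSS, 9027 ± 1044 with rTIMP2 from day 0 (adjusted p = 0.34) and 10052 ± 636 with rTIMP2 from day 7 (adjusted p = 0.83). The values cover the gene as a whole, so they do not separate parts of the transcript that the mutation may remove from those it keeps. In tumour lungs they also mix RNA of the host with RNA of the injected cells, the same line in both genotypes. They therefore do not show how Timp2 of the host tissue changed with tumour.

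**Figure D1:**
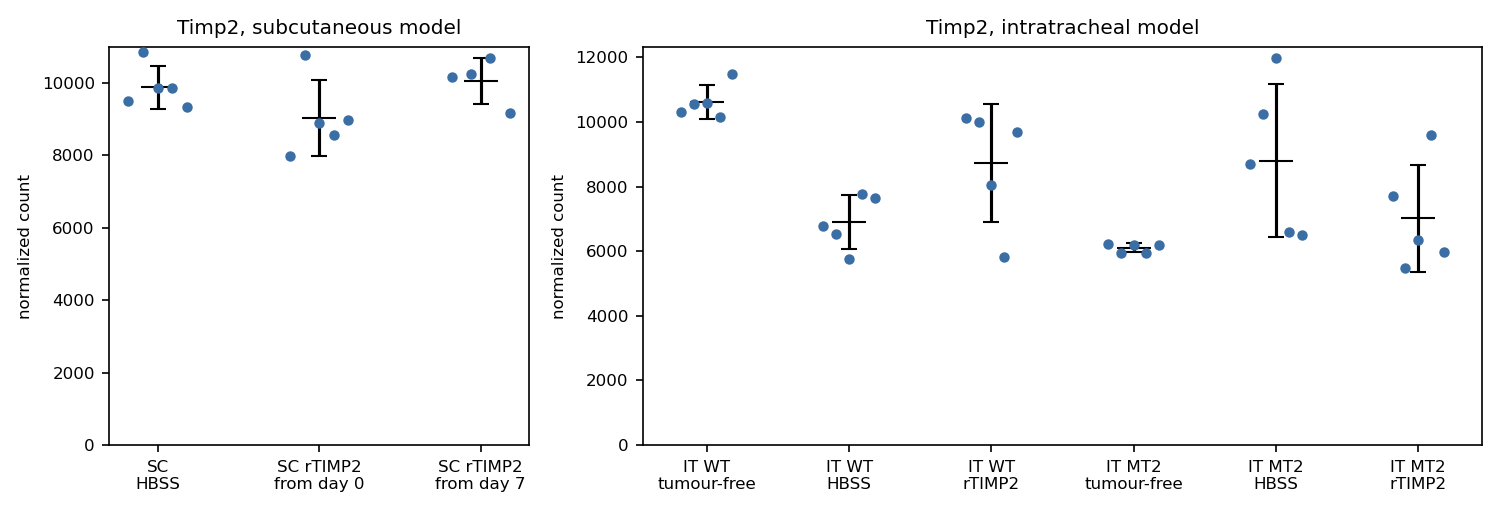
Normalized count of Timp2 (y axis, from 0) in each lung by group (x axis), with the subcutaneous model in one panel and the intratracheal model in the other; points are lungs and bars are group means with SD. Tumour-free MT2 lungs average 6105 and tumour-free WT lungs 10619, while the tumour-bearing groups of the intratracheal model spread more widely.

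The luciferase reporter Luc2 was listed at 0 in all 10 tumour-free lungs. In HBSS tumour lungs of the intratracheal model it averaged 51.1 ± 11.9 in WT and 59.8 ± 8.59 in MT2 mice (exact permutation p = 0.0079 against tumour-free lungs for each, and 0.2 between the genotypes). The treated WT lungs were uneven, with Luc2 at 23.3, 0, 0, 67.7 and 0 in replicates 1 to 5 (exact permutation p = 0.04 against HBSS, 0.12 after adjustment). Treated MT2 lungs had 75.5, 0.983, 50.9, 37.9 and 55.3 (exact permutation p = 0.25). Hmga2, a chromatin protein gene of embryonic and tumour cells, averaged 3704 ± 941 in WT and 4029 ± 917 in MT2 HBSS tumour lungs, against 17.9 ± 5.78 and 12.1 ± 2 in the tumour-free lungs. Treated WT lungs had 1198, 23.5, 32.1, 2780 and 13.6 (exact permutation p = 0.016), and treated MT2 lungs 5300, 63.9, 3309, 4378 and 3112 (exact permutation p = 0.52). In the subcutaneous model Luc2 averaged 20.5 ± 6.77 with HBSS, 26.4 ± 11.7 with rTIMP2 from day 0 and 27.4 ± 9.9 with rTIMP2 from day 7 (exact permutation p = 0.38 and 0.24 against HBSS). Hmga2 in those lungs averaged 3.89 ± 2.08 with HBSS and 10.4 ± 2.87 and 11.7 ± 4.95 with rTIMP2 (exact permutation p = 0.0079 and 0.024, adjusted 0.024 and 0.043). These means rest on few reads and lie below the 17.9 and 12.1 of the tumour-free intratracheal lungs, whose values were deposited separately. They are therefore not read as tumour content.

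Genes of the sex chromosomes also separated the groups. The Y-linked Ddx3y ranged from 0.91 to 5.78 in tumour-free lungs, where Xist, the RNA of the inactive X chromosome, ranged from 4118 to 6657. WT HBSS tumour lungs had both, with Ddx3y at 209 to 672 and Xist at 2399 to 6691, and so did MT2 HBSS tumour lungs, with Ddx3y at 123 to 525 and Xist at 1153 to 8305. Treated WT lungs had Ddx3y of 686, 1024, 1067, 633 and 1321 and Xist of 1963, 42.2, 92.4, 2033 and 54.5. Treated MT2 replicate 2 had Ddx3y of 1265 and Xist of 119. All subcutaneous lungs had high Ddx3y (1139 to 1714) and low Xist (3.75 to 40.8). These genes were chosen after their values were seen, and the labels used here give no sex per mouse.

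**Figure D2:**
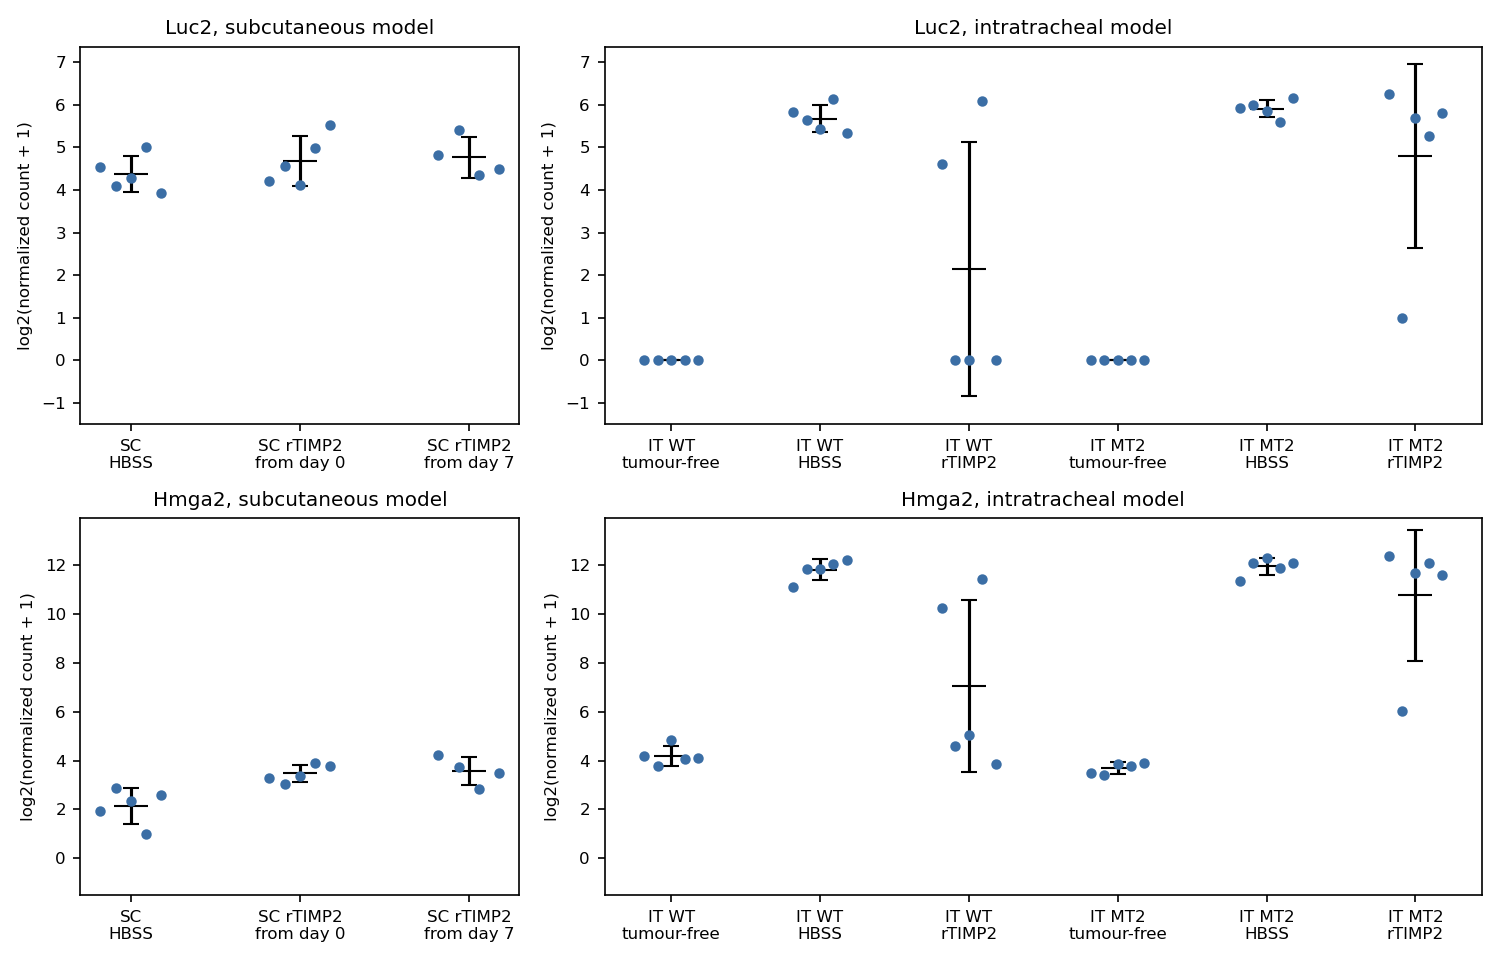
Log2 of the normalized count plus 1 (y axis) of the reporter Luc2 and of Hmga2 in each lung by group (x axis) of the subcutaneous and intratracheal models; points are lungs and bars show mean with SD. Tumour-free lungs sit at 0 for Luc2, and 3 of the 5 treated WT lungs sit there too.

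In the subcutaneous model, lungs of mice given rTIMP2 from day 0 had lower transcripts of several chaperone genes than HBSS lungs. Hspa1a, an inducible chaperone of stressed cells, fell from 4417 ± 1835 (SD, n = 5) to 504 ± 165 (n = 5), a log2 fold change of -3.09 ± 0.33 (SE, limma adjusted p = 0.0012). Its near-identical neighbour Hspa1b changed by -3.45 ± 0.34, Hsph1 by -2.44 ± 0.19 and the co-chaperones Dnajb1 and Dnaja1 by -1.66 ± 0.10 and -1.58 ± 0.12, with adjusted p of 0.00078 or less. The orphan nuclear receptor gene Nr4a3 fell by 2.75 and Klf4, a transcription factor of epithelium and endothelium, by 1.16 on the log2 scale. Among the largest rises were Ankrd63 (299.5 ± 37.4 to 813 ± 116, log2 1.43 ± 0.11, adjusted p = 7.9e-06), the calcium/calmodulin kinase subunit gene Camk2b (log2 1.40 ± 0.18), the urea transporter gene Slc14a1 (1.63 ± 0.32) and Carmn, a long non-coding RNA of muscle cells (1.86 ± 0.28).

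By list, 5 of 18 immediate early and tissue stress genes were lower (Hspa1a, Hspa1b, Klf4, Atf3 and Jund), 1 was higher (Ier3, log2 0.75 ± 0.099) and 12 did not pass. Of 20 hypoxia and glycolysis genes, P4ha1 (log2 -0.83 ± 0.13) and Adm fell and Pdk1 rose (0.33 ± 0.078). In the list of candidate tumour cell transcripts (11 tested), Krt8 (-0.49 ± 0.077) and Areg (-1.15 ± 0.24) were lower and Igf2bp1 (0.65 ± 0.16) was higher. Extracellular matrix genes had 3 of 27 lower, which were the crosslinking enzymes Loxl1 (-0.40 ± 0.091) and Lox (-0.48 ± 0.11) and the matricellular gene Ccn2 (-0.38 ± 0.094). Of 14 alveolar type 2 cell markers, the surfactant genes Sftpd (-0.39 ± 0.075) and Sftpc (-0.35 ± 0.098) were lower over all genes, and 6 members were lower adjusted over the list alone (camera adjusted p = 0.0015, adjusted p = 0.88 with an estimated correlation). Of 29 metalloproteinase and inhibitor genes, Adamts9 was lower (-1.16 ± 0.27), and of 23 suppressive myeloid genes Msr1 was higher (1.10 ± 0.32). T cell markers had Tcf7 higher (0.40 ± 0.081), with 17 of 18 log2 values positive and 3 members higher adjusted over the list alone. No B cell marker of 15 passed over all genes, though all 15 had positive log2 values. Single called members outside the naming rule (Atf3, Jund, Sftpd, Sftpc, Adamts9, Msr1 and Tcf7) were chosen after their values were seen, and the calls of Jund, Sftpc, Adamts9 and Msr1 were lost when single libraries were left out (adjusted p up to 0.088, 0.1, 0.075 and 0.11).

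Transcripts of neighbouring tissues moved with this comparison. Of 11 cardiac muscle genes, Ryr2 (log2 -0.57 ± 0.13) and Myl4 (-0.87 ± 0.23) were lower over all genes and 10 were lower adjusted over the list alone, and the mesothelial gene Wt1 was lower (-2.08 ± 0.47). These 3 genes were chosen after their values were seen, and the calls of Myl4 (adjusted p up to 0.11) and Wt1 (up to 0.061) were lost when single libraries were left out. HBSS replicate 1 had Krt13, a keratin of squamous epithelium, at 21180 against 97.07 to 140.8 in the other HBSS lungs. In all, limma called 1399 of 17282 genes, 671 higher and 728 lower with rTIMP2 from day 0. The count fell to 871 without HBSS replicate 2, to 911 without HBSS replicate 3 and to 861 without day 0 replicate 4, and it rose to 2297 with all subcutaneous groups in 1 fit. The calls of Adm (adjusted p = 0.052), Lox (up to 0.056), Ccn2 (up to 0.065) and Igf2bp1 (up to 0.058) were lost when single libraries were left out.

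With rTIMP2 from day 7, Hspa1a and Hspa1b were lower than with HBSS as well. Hspa1a averaged 459 ± 135 (SD, n = 4), a log2 fold change of -3.21 ± 0.35 (SE, adjusted p = 0.0035), and Hspa1b changed by -3.24 ± 0.38. The stress transcription factor gene Atf3 fell from 546.5 ± 115 to 242 ± 31.6 (log2 -1.15 ± 0.16, adjusted p = 0.0024) and Has1, a hyaluronan synthase gene, from 111.8 ± 32.5 to 17.8 ± 4.81 (log2 -2.55 ± 0.26). Calcrl, a receptor gene of endothelial cells, rose from 13877 ± 1406 to 21261 ± 1500 (log2 0.62 ± 0.082, adjusted p = 0.0012). The basal keratin gene Krt17 rose by 1.70 ± 0.27, Ankrd63 by 1.02 ± 0.11 and the DNA demethylase gene Tet1 by 1.09 ± 0.14 on the log2 scale.

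Surfactant and other alveolar type 2 genes were lower as a group, with 7 of 14 called and 11 adjusted over the list alone (camera adjusted p = 7.3e-05, adjusted p = 0.87 with an estimated correlation). Sftpc fell from 219495 ± 14893 to 170008 ± 10750 (log2 -0.37 ± 0.079), and Sftpd and the lipid transporter gene Abca3 changed by -0.38 ± 0.058 and -0.37 ± 0.072. Immediate early and tissue stress genes had 7 of 18 lower and Ier3 higher (0.39 ± 0.11), and 13 were lower adjusted over the list alone (adjusted p = 0.87 with an estimated correlation). Among metalloproteinase genes and inhibitors, Timp1 fell from 68.6 ± 6.61 to 39.1 ± 7.35 (log2 -0.81 ± 0.17), Adamts1 (-0.39 ± 0.079) and Mmp15 (-0.21 ± 0.06) were lower, and Mmp28 was higher (0.55 ± 0.11), while 25 of 29 did not pass. Of 24 type I interferon genes, Ifit3 rose from 920.0 ± 157 to 1396 ± 34.1 (log2 0.62 ± 0.11), Ddx58 (0.29 ± 0.066) and Ifit2 (0.31 ± 0.093) were higher and none was lower. Of 20 monocyte and interstitial macrophage markers, Apoe (-0.45 ± 0.074), C1qc (-0.65 ± 0.15) and C1qb (-0.61 ± 0.17) were lower. The urokinase receptor gene Plaur was lower (-0.79 ± 0.13).

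Of 8 mesothelial genes Wt1, Upk3b and Lrrn4 were called lower and 5 were lower adjusted over the list alone (camera adjusted p = 0.0028, adjusted p = 0.93 with an estimated correlation). Wt1 was at 8.43 ± 4.02 against 70.1 ± 44.9 in HBSS lungs (log2 -2.75 ± 0.51, adjusted p = 0.009) and Upk3b at 200.4 ± 89.5 against 1295 ± 746 (log2 -2.55 ± 0.58, adjusted p = 0.036), and Lrrn4 changed by -2.64 ± 0.67 (adjusted p = 0.047). Of 11 cardiac muscle genes 8 were lower adjusted over the list alone, of which Tnni3 (-0.61 ± 0.13), chosen after its value was seen, passed over all genes. In all, 1805 of 17389 genes were called, 776 higher and 1029 lower. The count fell to 1068, 834, 1050 and 873 when day 7 replicates 1, 2, 3 and 4 were left out in turn. The call of Upk3b was lost in some of these fits (adjusted p up to 0.1) and with voom (0.075), that of Wt1 with voom (0.066), that of Lrrn4 in several (up to 0.12 with 1 library left out and 0.17 with voom), and those of C1qb, C1qc, Ddx58, Ier3, Ifit2 and Mmp15 in at least 1 fit.

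Lungs treated from day 7 were also compared with those treated from day 0. The chaperone genes Chordc1 and Hsph1 were higher with the later start, with Chordc1 at 1063 ± 29.5 against 739 ± 53.7 (log2 0.53 ± 0.067, adjusted p = 0.005) and Hsph1 at 1682 ± 425 against 716 ± 82.9 (log2 1.20 ± 0.16, adjusted p = 0.026), while Hspa1a (-0.12, adjusted p = 0.89) and Hspa1b (0.21, adjusted p = 0.75) did not pass. The phosphodiesterase gene Pde4b rose by 0.82 ± 0.087 on the log2 scale (adjusted p = 0.0015). Immediate early transcription factor genes were lower, with Egr1 at 853 ± 255 against 3173 ± 682 (log2 -1.91 ± 0.24, adjusted p = 0.032) and Ier2 at 1307 ± 125 against 2350.0 ± 302 (log2 -0.84 ± 0.092, adjusted p = 0.0015). HBSS lungs had Egr1 at 2041 ± 1603. The cold-inducible gene Cirbp was at 955 ± 88.9 with the later start, 1581 ± 247 with the earlier one (log2 -0.72 ± 0.11, adjusted p = 0.015) and 764 ± 122 with HBSS. Of 18 immediate early and stress genes, Egr1, Ier2 and Ier3 were lower and Klf4 was higher over all genes, and 11 were lower adjusted over the list alone (camera adjusted p = 1e-08, adjusted p = 0.15 with an estimated correlation). Limma called 41 of 17481 genes, 27 higher and 14 lower, and 2249 had an unadjusted p under 0.05. The count ranged from 8 without day 7 replicate 2 to 65 without day 0 replicate 1, also falling to 16 and 25 without day 0 replicates 3 and 4 and to 10 and 19 without day 7 replicates 1 and 3, and the calls of Egr1 (adjusted p up to 0.16) and Hsph1 (up to 0.076) did not hold in all of these.

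**Figure D3:**
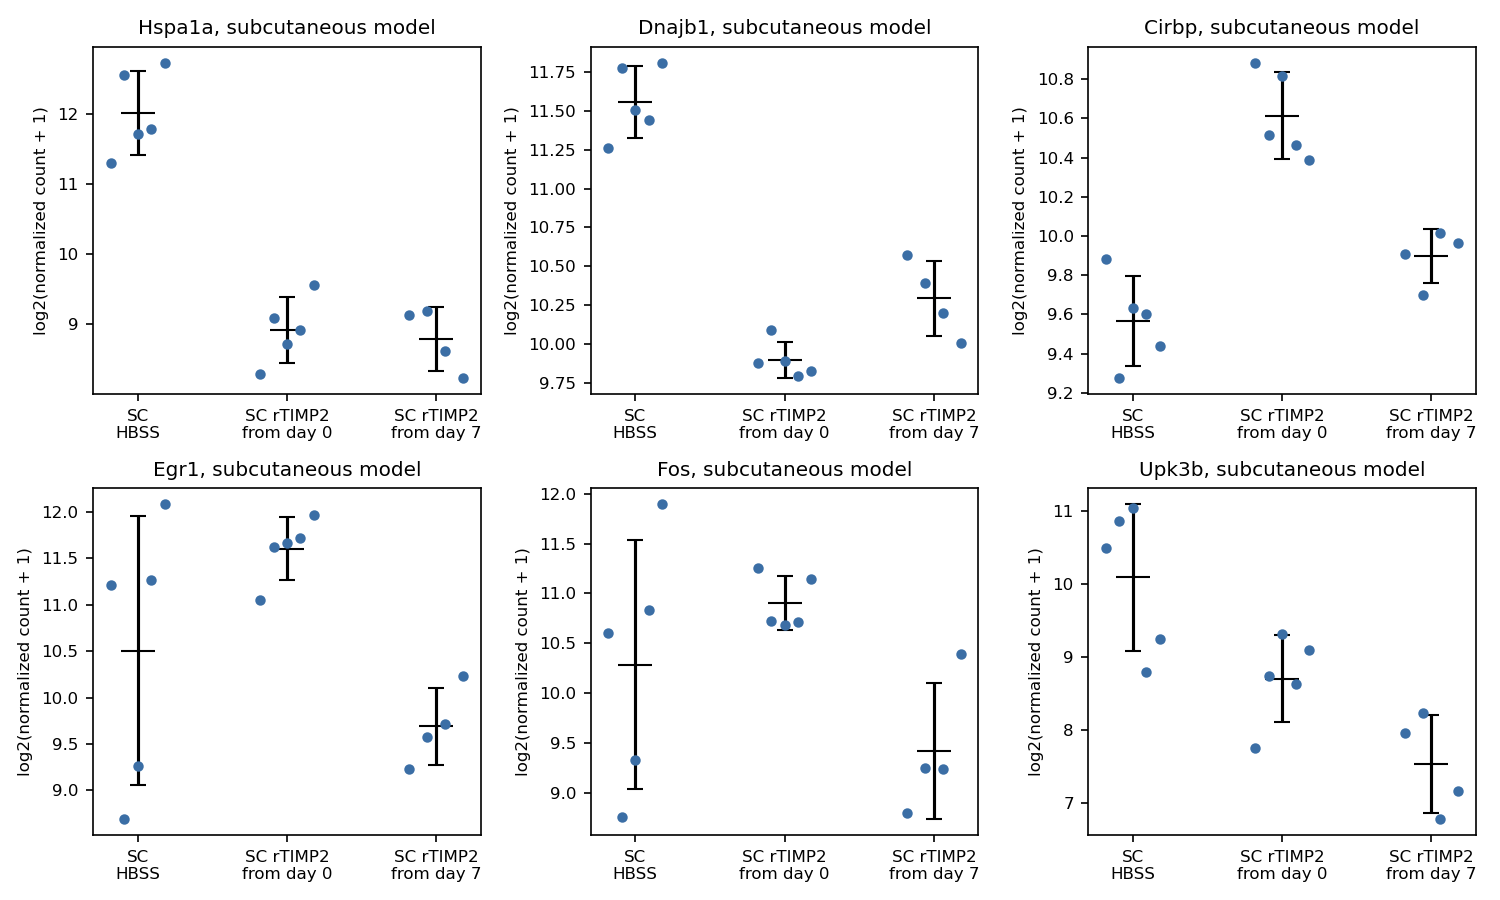
Log2 of the normalized count plus 1 (y axes, not starting at 0) of Hspa1a, Dnajb1, Cirbp, Egr1, Fos and Upk3b in each lung of the 3 subcutaneous groups (x axes); points are lungs and bars show mean with SD. Hspa1a averages 4417 with HBSS against 504 and 459 with rTIMP2, and Egr1 is lower with the start at day 7 (853) than at day 0 (3173).

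Both treated groups were compared with the same 5 HBSS lungs, so their effects share the controls' spread. Over 17169 genes tested in both, 316 were higher in both and 350 lower in both, against 30 and 43.5 for independent lists, and 0 were called in opposite directions. The log2 fold changes correlated across genes at r = 0.75, where 100 simulations with shared controls and no effect gave a median of 0.48 and a highest value of 0.78. Their covariance was 0.079 against a highest simulated value of 0.043. With the HBSS lungs split so that each treated group had its own controls, r had a median of 0.46 over 10 splits (0.37 to 0.51). Genes are not independent replicates in these correlations.

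WT lungs given intratracheal tumour cells with HBSS differed from tumour-free WT lungs in most genes tested. Transcripts of proliferation rose, with the mitotic kinase gene Plk1 at 536 ± 129 (SD, n = 5) against 38.7 ± 6.57 in tumour-free lungs (n = 5, log2 3.74 ± 0.19). The largest rises included Hmga2 (log2 7.62 ± 0.23, adjusted p = 2e-08), the AP-1 factor gene Fosl1 (8.26 ± 0.43, adjusted p = 2.8e-07), the homeobox gene Rhox5 (7.39 ± 0.40) and Lrrc15, a membrane protein gene of activated stroma (7.53 ± 0.50). The largest falls included Colq (-5.30 ± 0.73), Tril (-4.76 ± 0.52) and Mamdc2 (-4.64 ± 0.57). Endothelial cadherin Cdh5 fell from 13417 ± 989 to 1965 ± 1267 (log2 -2.97 ± 0.32), and Scgb1a1, the main secretory protein gene of club cells, from 317331 ± 21341 to 46149 ± 57550 (-3.60 ± 0.67).

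Among lists that rose, 30 of 30 proliferation genes were higher, 17 of 20 hypoxia and glycolysis genes were higher and 1 lower (Egln3 4.91 ± 0.24 and Ldha 1.96 ± 0.12, against Pfkfb3 -1.41 ± 0.28), and 13 of 22 cytokine and chemokine genes were higher and 3 lower (Ccl2 5.97 ± 0.29 and Ccl7 5.56 ± 0.22, against Il1a, Csf2 and Tslp). Monocyte and interstitial macrophage markers had 12 of 20 higher and 4 lower, with the complement gene C1qc at 2314 against 423 (log2 2.43 ± 0.16). Suppressive myeloid genes went both ways, 9 of 23 higher, such as Spp1 (1023 ± 451 to 15113 ± 3740, log2 3.94 ± 0.28), Msr1 (3.62 ± 0.23) and Gpnmb (2.73 ± 0.18), and 6 lower, such as Vegfa (-2.29 ± 0.29). Metalloproteinase genes and inhibitors had 10 of 29 higher, such as Timp1 (58.2 ± 11.7 to 536 ± 194, log2 3.13 ± 0.23) and Adam8 (2.32 ± 0.14), and 15 lower, such as the inhibitor gene Reck (-3.22 ± 0.38), Mmp15 (-3.80 ± 0.52) and Mmp2 (-2.94 ± 0.42). Matrix genes had 8 of 27 higher, with Thbs2 at 5.79 ± 0.23, and 17 lower, with Loxl1 at -2.79 ± 0.24. Transition genes of epithelium to mesenchyme had 10 of 16 higher (Twist1 6.03 ± 0.27, S100a4 4.44 ± 0.33) and 5 lower (Zeb1, Zeb2, Itgb1, Tgfb1 and Mmp2).

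The tumour lungs also hold RNA of the injected cells, and values are normalized per library. Falls here and in MT2 mice therefore do not separate dilution of host RNA from loss of cells or a tissue response. Rises likewise do not separate host transcripts from those of the injected cells. Markers of normal lung cells fell together. All 16 endothelial, 14 alveolar type 2, 14 alveolar type 1 and 14 ciliated cell markers were lower, as were 9 of 11 club cell markers and 12 of 14 fibroblast markers, of which Dcn rose (2.26 ± 0.24). Lymphocyte transcripts fell as well, with 15 of 18 T cell, 13 of 15 B cell and 13 of 14 NK and cytotoxic genes and 10 of 10 MHC class II genes lower (Gzma -3.36, Cd2 -2.48 and Cd74 -1.82 ± 0.38 on the log2 scale). Of the alveolar macrophage markers 12 of 15 were lower, including Chil3 (-2.78 ± 0.29). Squamous keratin gene Krt4 was at 6015 ± 8778 against 18.8 ± 35.1, and Krt13 was at 22600.0 and 9776 in HBSS replicates 1 and 4. Limma called 11962 of 16967 genes, 5571 higher and 6391 lower. Lists called by camera had adjusted p of 0.58 to 0.66 with an estimated correlation, and the calls of Krt4, Krt13, Itgb1 and Tgfb1 were lost in at least 1 alternative.

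In MT2 mice the same contrast called 11457 of 16999 genes, 5360 higher and 6097 lower. Rhox5 rose from 9.44 ± 4.26 to 3214 ± 811 (log2 8.34 ± 0.30), Hmga2 by 8.25 ± 0.19 (adjusted p = 9.3e-10) and Arg1, the arginase gene of suppressive myeloid cells, from 35.0 ± 4.73 to 1740.0 ± 521 (5.56 ± 0.20, adjusted p = 2.3e-08). Other myeloid genes rose too, among them the lipid receptor gene Trem2 (3.55 ± 0.15), Msr1 (3.79 ± 0.21) and C1qb (2.91 ± 0.13), and 12 of 20 monocyte and interstitial macrophage markers were higher and 5 lower. All 30 proliferation genes were higher, with Cdk1 at 972 against 62.5 (3.91 ± 0.23), and 13 of 20 hypoxia and glycolysis genes were higher, with Gapdh at 2.59 ± 0.14 and Eno1 at 2.51 ± 0.12, and 2 were lower (Pfkp and Pfkfb3). The membrane-bound metalloproteinase gene Mmp14 rose by 2.59 ± 0.24, while Reck (-3.69 ± 0.25), Mmp2 (-4.04 ± 0.32) and Mmp15 (-4.93 ± 0.41) fell. Lymphocyte and antigen presentation genes were lower, with 17 of 18 T cell, 15 of 15 B cell, 13 of 13 NK and cytotoxic and 10 of 10 MHC class II genes called. Ciita, the master regulator of MHC class II, fell from 551 ± 108 to 23.5 ± 10.6 (-4.58 ± 0.29), Cd79a of the B cell receptor by 4.80 and the granzyme gene Gzma by 5.54 on the log2 scale. All tested endothelial (16), alveolar type 2 (14), alveolar type 1 (14), club (11) and ciliated (14) markers were lower, with Cdh5 at -4.10 ± 0.26. Lists called by camera had adjusted p of 0.34 to 0.69 with an estimated correlation.

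The tumour effects of the genotypes were alike across genes. Over 16702 genes tested in both, 4581 were higher in both and 5365 lower in both, against 1728 and 2268 for independent lists, and 7 were called in opposite directions. The log2 fold changes correlated across genes at r = 0.96 with a slope of 1.1. Tumour-free and tumour-bearing lungs also differed in sex chromosome transcripts, as given above for Ddx3y and Xist.

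Tumour-free MT2 lungs differed little from tumour-free WT lungs. Besides Timp2, the small membrane protein gene Smim6 was lower (28.3 ± 4.62 against 180 ± 59.8, SD, n = 5 each, log2 -2.58 ± 0.19, adjusted p = 2.2e-06). The collagen chaperone gene Serpinh1 (5728 ± 187 against 4482 ± 355, log2 0.36 ± 0.055) and the collagen crosslinking gene Loxl2 (890.5 ± 63.2 against 652 ± 56.8, log2 0.45 ± 0.07) were higher, with adjusted p of 0.034 each. Nid2, a basement membrane gene with the next smallest p, had a log2 fold change of 0.52 ± 0.089 (adjusted p = 0.073). Matrix genes leaned the same way, with 24 of 27 log2 values positive, 1 called over all genes (Loxl2) and 14 higher adjusted over the list alone (camera adjusted p = 4.2e-13, adjusted p = 0.27 with an estimated correlation). Proliferation genes had 28 of 30 log2 values positive, 4 of them higher adjusted over the list alone, and NK and cytotoxic genes had 14 of 14 negative (adjusted p = 0.57 and 0.56 with an estimated correlation). Metalloproteinase genes and inhibitors had 26 of 30 positive, and Timp2 itself was the called member.

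Smim6 lies on chromosome 11, 2.39 Mb from Timp2. Of 209 tested genes within 10 Mb of Timp2, 30 (14.4%) had an unadjusted p under 0.05, against 1603 of 16565 elsewhere (9.68%). Between MT2 and WT HBSS tumour lungs the share was lower near Timp2, 12 of 202 (5.94%) against 1196 of 16097 elsewhere (7.43%). Limma called 4 of 16774 genes between tumour-free MT2 and WT lungs, 2 higher and 2 lower, and 1633 had an unadjusted p under 0.05. Leaving out 1 library gave 2 calls (MT2 tumour-free replicate 1, 2 or 5 or WT tumour-free replicate 2) to 9 calls (MT2 tumour-free replicate 4), in which Loxl2 and Serpinh1 reached adjusted p of 0.14, and with all 6 intratracheal groups in 1 fit 0 genes were called (Timp2 at -0.80 with an SE of 0.17, adjusted p = 1).

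Between HBSS tumour lungs of MT2 and WT mice, limma called 0 of 16299 genes, with 1208 at an unadjusted p under 0.05 and 0 called by voom. The smallest p belonged to Apln, a peptide ligand gene of endothelium, at 260 ± 93.6 in MT2 and 896 ± 173 in WT lungs (SD, n = 5 each, log2 -1.83 ± 0.25, adjusted p = 0.15). Next came Cd300ld (-2.44 ± 0.40, adjusted p = 0.35), Fam167a (-1.49), the lactate transporter gene Slc16a3 (-1.45) and Basp1 (-1.34). Immune transcripts had lower values in MT2 lungs, with 9 of 9 MHC class II, 9 of 12 B cell, 8 of 17 T cell and 4 of 5 NK and cytotoxic genes lower adjusted over the list alone (camera lost with an estimated correlation, adjusted p = 0.31 for MHC class II, B cell and NK genes and 0.41 for T cell genes). Ciita had means of 23.5 and 182 (log2 -2.52 ± 0.58, adjusted p = 0.42 over all genes). Matrix genes had 12 of 26 lower adjusted over the list alone (adjusted p = 0.31 with an estimated correlation), such as Acta2 (-1.74 ± 0.45) and Loxl2 (-1.22 ± 0.32). Ciita, Acta2 and Loxl2 were chosen here after their values were seen. With all intratracheal groups in 1 fit 135 genes were called, and with sample weights 6.

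The interaction of genotype with tumour, which asks whether the tumour effect differed between the genotypes, was called for 4 genes, all with a lower tumour effect in MT2 mice. Tumour-free and tumour-bearing lungs also differed in sex chromosome transcripts, so this contrast cannot tell tumour from sex or from a separate cohort. Serpinh1 went from 4482 to 10103 ± 1333 with tumour in WT and from 5728 to 6473 ± 344 in MT2 mice (difference in log2 fold change -0.99 ± 0.14, n = 5 per group, adjusted p = 0.0088). The others were Apln (-1.94 ± 0.27, adjusted p = 0.0088), Fam167a (-1.59 ± 0.25, adjusted p = 0.023) and the endothelial protocadherin gene Pcdh12 (-1.85 ± 0.31, adjusted p = 0.032). Timp2 had a difference of 1.12 ± 0.20 (adjusted p = 0.089). Adjusted over the list alone, 10 of 10 MHC class II, 10 of 18 T cell, 9 of 15 B cell and 13 of 27 matrix genes had lower tumour effects in MT2 mice (adjusted p of 0.3 or more with an estimated correlation). The count of 4 ranged from 2 to 55 when 1 library was left out and was 0 with all 6 groups in 1 fit. It was 49 and 55 without MT2 HBSS replicates 4 and 5, 10 and 21 without WT HBSS replicates 3 and 5, and 2 without WT HBSS replicate 2 or 4, MT2 tumour-free replicate 1, 3, 4 or 5 or WT tumour-free replicate 1, 4 or 5.

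In WT tumour lungs, rTIMP2 was followed by values nearer those of tumour-free lungs, unevenly between mice. Fosl1 averaged 173 against 992 with HBSS (log2 -4.71 ± 1.3), Adam8 447 against 1360.0 (-1.75 ± 0.33) and the receptor gene Il1rl1 349.5 against 1594 (-3.07 ± 0.69), with n = 5 each and adjusted p = 0.04. Higher with rTIMP2 were the lectin gene Mgl2 of macrophages (271 ± 55.1 against 92.7 ± 64.7, SD, log2 1.78 ± 0.42), Rd3 (3.08 ± 0.56) and the neuropeptide gene Grp (2.16 ± 0.45). Reck rose from 172 ± 137 to 787 ± 397 (2.18 ± 0.62). Smim6 was at 204 against 77.5 (1.73 ± 0.55, adjusted p = 0.044).

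By list, 15 of 16 endothelial, 14 of 14 alveolar type 1, 12 of 14 alveolar type 2, 12 of 14 ciliated and 8 of 11 club cell markers were higher (Calcrl 2.67 ± 0.60, Scgb1a1 2.93 ± 0.80), as were 11 of 15 B cell, 6 of 18 T cell and 5 of 14 NK and cytotoxic genes and 9 of 10 MHC class II genes. Adjusted over the list alone these were 16, 14, 14, 14 and 8 for the lung cell types and 14, 8, 8 and 10 for the immune lists. Lower were 25 of 30 proliferation genes (30 adjusted over the list alone; Mki67 at 553 against 2103, -2.25 ± 0.55), 10 of 20 hypoxia and glycolysis genes (Slc2a1 -1.86) and 9 of 22 cytokine genes, with Il1a higher. Metalloproteinase genes and inhibitors had 5 of 29 higher (Reck, Mmp15, Timp3, Mmp23 and Adamts5) and 6 lower, among them Mmp19 and Mmp3 (-0.78 and -0.75). Suppressive myeloid genes had 3 higher (Vegfa, Ccl17 and Ccl22) and 6 lower, among them Ptgs2 (-1.41 ± 0.30) and Nos2 (-1.45). Lists called by camera had adjusted p of 0.57 to 0.6 with an estimated correlation. The libraries of replicates 2 and 3 held Krt13 at 37270.0 and 114400.0, against 61.21 to 93.34 in the other treated lungs.

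Limma called 4619 of 16908 genes, 2702 higher and 1917 lower, with a smallest adjusted p of 0.04 and 8032 at an unadjusted p under 0.05. With 1 library left out, 0 genes were called without WT HBSS replicate 2, 3, 4 or 5 or without WT rTIMP2 replicate 1, 2, 3 or 5, while 7308 were called without HBSS replicate 1 and 9584 without rTIMP2 replicate 4. Voom on the estimated reads, the reporter as a covariate and leaving out the libraries high in squamous or muscle transcripts also gave 0 each.

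On a scale set by 6015 genes, where 0 is the tumour-free mean and 100 the HBSS tumour mean of the genotype, treated WT lungs lay at 35.6, 7.04, 18.6, 90.2 and 0.971%. HBSS WT lungs lay at 54.2, 107, 116, 92.5 and 131%, and the tumour-free lungs of both genotypes at -2.83 to 3.92%. Treated MT2 lungs lay at 97.5, 6.17, 82, 84.9 and 78.5%, and HBSS MT2 lungs at 118, 114, 100, 78.7 and 88.9%. Across 16643 genes tested in both WT comparisons, 1851 were higher with tumour and lower with rTIMP2 and 2661 lower with tumour and higher with rTIMP2, against 632 and 997 for independent lists. Another 4 were higher in both and 1 lower in both. The effects correlated across genes at r = -0.95, where simulations with the shared HBSS lungs and no effect reached -0.94. The covariance was -1.6 against a lowest simulated value of -0.4, and with split HBSS lungs r had a median of -0.9 (-0.94 to -0.75).

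**Figure D4:**
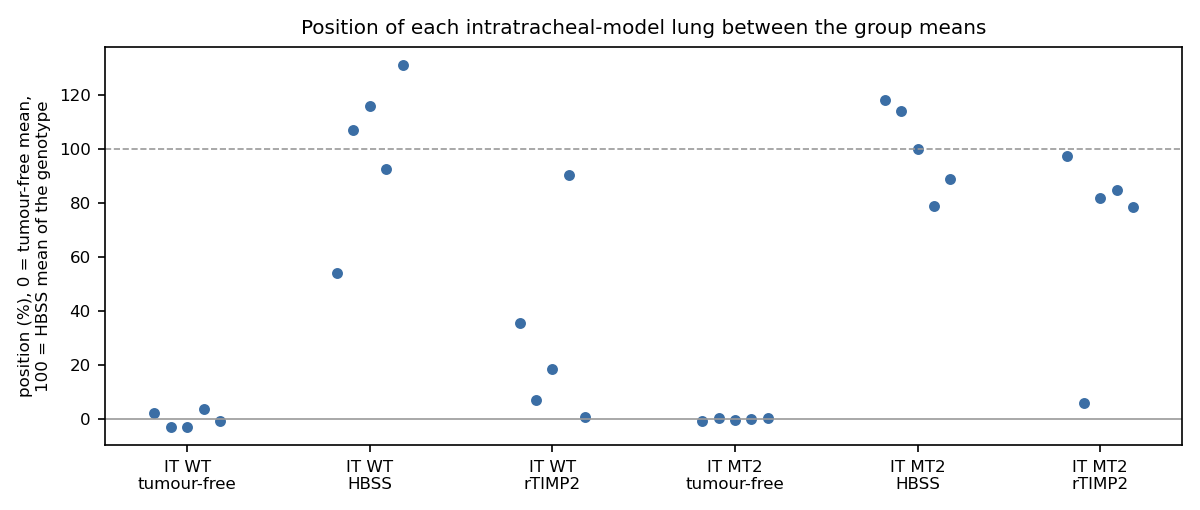
Position of each intratracheal lung on the tumour scale in percent (y axis), where 0 is the mean of tumour-free lungs and 100 the mean of HBSS tumour lungs of the same genotype, by group (x axis); points are lungs. Treated WT lungs spread from 0.971 to 90.2%, and 4 of the 5 treated MT2 lungs lie between 78.5 and 97.5% with replicate 2 at 6.17%.

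In MT2 tumour lungs limma called 0 of 16248 genes between rTIMP2 and HBSS, with 1559 at an unadjusted p under 0.05 and 0 called by voom. The smallest p belonged to Itgae, an integrin gene of tissue-resident lymphocytes and dendritic cells, at 57.1 ± 9.11 with rTIMP2 against 9.57 ± 1.28 with HBSS (SD, n = 5 each, log2 2.45 ± 0.30, adjusted p = 0.053). Ciita was at 236 ± 169 against 23.5 ± 10.6 (3.09 ± 0.50, adjusted p = 0.18). The metallothionein genes Mt1 (-1.66 ± 0.25) and Mt2 (-2.21), and Fam167a (1.73), followed with the same adjusted p. Immune lists had higher values with rTIMP2 adjusted over the list alone, in 10 of 10 MHC class II, 13 of 17 T cell, 10 of 12 B cell, 6 of 6 NK and cytotoxic and 5 of 10 dendritic cell genes (adjusted p = 0.27 to 0.3 with an estimated correlation). Proliferation genes had 24 of 30 negative log2 values and 0 past the threshold adjusted over the list alone. With all intratracheal groups in 1 fit 661 genes were called, and with sample weights 468.

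The interaction of genotype with rTIMP2, which asks whether the treatment effect differed between WT and MT2 tumour lungs, was called for 0 genes by limma and 0 by voom, with 1053 at an unadjusted p under 0.05. The smallest p belonged to Slc16a3 (difference in log2 fold change 1.68 ± 0.35, n = 5 per group, adjusted p = 0.67), and Arrdc2 (-1.65), Pilra (1.46) and Cd300ld (2.29) had the same adjusted p. Proliferation genes had 30 of 30 positive differences, with 0 past the threshold adjusted over the list alone (camera adjusted p = 4.8e-14, adjusted p = 0.62 with an estimated correlation). Endothelial markers had 16 of 16 negative differences (camera adjusted p = 0.0011, 0.69 with an estimated correlation). Across 15950 genes tested in both genotypes, the rTIMP2 effects correlated at r = 0.72 with a slope of 0.43, across genes. Treated MT2 replicate 2, with a reporter of 0.983, lay at 6.17% of the tumour scale, far from the other treated MT2 lungs. The correlation was not computed without this lung, so how far it rests on it is not known. With 0 genes called in the interaction, a called effect in WT and none in MT2 lungs is not shown to be a difference between the genotypes.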

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

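The tests of tumour RNA content, of tumour cells not reaching the lungs, of temperature, of time of day and of sex with the WT HBSS lungs split were chosen after the results were seen, as were the 12 heat-shock genes and the condition that a reading hold with each library left out. The other tests in this part were set before the values they measure were seen.

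Mean log2 values of 8 gene lists of neighbouring tissues and blood, and the values of Luc2 and Timp2, were searched in every group for a library far from the others. Subcutaneous HBSS replicate 1 stood apart in squamous epithelium genes (9.12, others 5.11 to 5.77) and in skeletal muscle genes (9.91, others 4.27 to 4.45). Tumour-free WT replicate 5 stood apart in squamous epithelium genes (3.92, others 2.25 to 2.52) and tumour-free WT replicate 3 in erythroid genes (8.99, others 8.27 to 8.34). Treated WT replicate 3 of the intratracheal model stood apart in cartilage genes (4.07, others 1.34 to 2.10). Of 88 pairs of group and measure, 5 had such a library, and chance gives about 1 in 20, or 4.4.

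The difference between tumour-bearing and tumour-free lungs was unlike in the genotypes by the interaction test for Serpinh1 (-0.99), Apln (-1.94), Fam167a (-1.59) and Pcdh12 (-1.85, log2 difference of MT2 from WT). Whether sex or a separate cohort accounts for it was not tested for these genes. Of 100 splits of these samples, 7 called at least 4 genes and the highest other split called 1343, so chance is not excluded for this count.

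The contrast of tumour-bearing with tumour-free lungs carries a difference in sex, since tumour-free lungs had Xist at 4118 to 6657 and Ddx3y at most 5.78, while treated lungs with little reporter had the reverse. It may also carry a difference in cohort or batch, since the sample numbers of the tumour-free lungs lie in another range. If sex were the cause of the tumour calls, those genes would go either way within lungs given tumour cells, and the same holds for a separate cohort. Of 10727 autosomal genes called in MT2 mice, 97.9% had the opposite sign in the WT comparison of rTIMP2 with HBSS (97.1 to 98.1% with 1 library left out), which argues against sex as the cause for most of them. For WT mice the test in the MT2 lungs did not decide, with 76.3% of 10714 genes opposite in sign, 54.2% without treated MT2 replicate 2 and at most 81.9%. With the WT HBSS lungs split, so that the tumour calls and the comparison with rTIMP2 shared no lung, a median of 95.6% of the called autosomal genes had the opposite sign over 20 splits (88.8 to 98.2%, and at least 78.9% with 1 more library left out), which argues against sex for most WT calls as well and leaves open an effect of the tumour, which the design names.

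The genes called between rTIMP2 and HBSS in WT lungs had a median signed log2 fold change of 1.46 (median SE 0.41). With the squamous and muscle scores as a covariate 93.8% of it was kept (83 without treated replicate 5, at most 103, 4181 genes called), which argues against pieces of other tissue as the cause. With the reporter as a covariate 49.1% was kept (33.6 without treated replicate 1, at most 71.7), the median was 0.716 with an SE of 0.45, and 0 genes were called because the effect shrank while its error did not. A candidate explanation is therefore a different content of tumour RNA between lungs, which stays open, as do an effect of rTIMP2 on tumour growth and tumour cells that did not reach some lungs. Of the treated WT lungs 3 had a reporter value of 0, which clearance after arrival and failed delivery would both give.

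The 12 heat-shock genes, which were gathered after the pattern was seen (Ahsa1, Chordc1, Dnaja1, Dnajb1, Hsp90aa1, Hspa1a, Hspa1b, Hspa8, Hspd1, Hspe1, Hsph1 and Stip1), had a median log2 fold change of -1.20 with rTIMP2 from day 0 and -0.651 from day 7. For day 0, pieces of heart, fat and mesothelium in the HBSS libraries are argued against, since 102% of the median was kept with their scores as a covariate (91.7 without HBSS replicate 1, at most 124, with 12 of 12 genes called lower). For day 7 that test stays open (92.1% kept, 70.1 without HBSS replicate 1 and at most 130, with 3 genes called against 11 without the covariate, as the median SE went from 0.15 to 0.24 and the median to -0.6). A lower temperature of the lungs at collection may account for the day 0 values, since the cold-induced gene Cirbp was higher (1.05 ± 0.12, adjusted p = 0.00023), but Rbm3 did not pass (0.19 ± 0.083, adjusted p = 0.17), and for day 7 Rbm3 was lower (-0.25 ± 0.07, adjusted p = 0.034, but 0.073 without HBSS replicate 3 and 0.095, 0.12 and 0.084 without day 7 replicates 1, 2 and 3), so temperature stays open for both. The clock contrast differed from HBSS by 0.44 (exact permutation p = 0.063) and 0.18 (exact permutation p = 0.5), against an SD of 0.41 between HBSS lungs, so the time of day and an effect of rTIMP2 itself stay open.

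Gene counts were compared with 100 splits of the same samples, the real split counted among those as large. No other split reached the real count for rTIMP2 from day 0 (1 split as large, 1399 real, 80 highest other), from day 7 (1 split, 1805, 490), tumour in WT (1 split, 11962, 6006) and in MT2 mice (1 split, 11457, 1). Fewer than 1 in 20 splits were as large for day 7 against day 0 (2 splits, 41, 66), MT2 against WT tumour-free lungs (3 splits, 4, 5) and rTIMP2 in WT tumour lungs (2 splits, 4619, 5591). In each of these latter comparisons another split called more genes than the real one, so chance is not ruled out there. Chance is also not excluded where 0 genes were called, which held for MT2 against WT HBSS lungs (100 splits, highest other 1), rTIMP2 in MT2 lungs (100 splits, highest other 2) and the interaction with rTIMP2 (100 splits, highest other 2610). Some splits called far more genes than the real one, such as 1343 for the interaction with tumour and 2610 for that with rTIMP2. What sets these splits apart was not tested.

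Counts of lists called by camera were reached by many other splits, so chance is excluded for none of them. The number of splits as large, with the real count and the highest other, was 71 for rTIMP2 from day 0 (11 and 25), 77 from day 7 (10 and 23) and 98 for day 7 against day 0 (4 and 25). It was 35 for tumour in WT mice (19 and 27) and 22 in MT2 mice (23 and 27), 61 for MT2 against WT tumour-free lungs (9 and 20) and 14 for HBSS lungs (23 and 29). For rTIMP2 it was 9 in WT lungs (25 and 27) and 46 in MT2 lungs (17 and 27), and for the interactions 16 with tumour (21 and 28) and 31 with rTIMP2 (18 and 27).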

How the results depend on the processing

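Voom on the estimated reads, leaving out libraries high in squamous or muscle transcripts, and the reporter as a covariate were chosen after the data were seen. The planned edgeR and DESeq2 alternatives were not run, since whole reads could not be recovered.

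Other pseudocounts, no filter and both rescalings kept every gene count within 1.5 times its value, except that a pseudocount of 5 called 1 gene for rTIMP2 in MT2 lungs, where 0 were called. With all groups of a table in 1 fit, 2297 genes were called for rTIMP2 from day 0, 0 for MT2 against WT tumour-free lungs, 135 for MT2 against WT HBSS lungs, 8192 and 661 for rTIMP2 in WT and MT2 lungs, and 0 for the interaction with tumour. Sample weights gave 2210 for rTIMP2 from day 0, 106 for day 7 against day 0, 6 for MT2 against WT HBSS lungs, 12190 and 468 for rTIMP2 in WT and MT2 lungs, and 187 and 8147 for the interactions with tumour and with rTIMP2. For rTIMP2 in WT lungs voom, the reporter as a covariate and leaving out libraries high in squamous or muscle transcripts gave 0 each, and leaving out such libraries gave 27 for the interaction with tumour. The cause was not tested.

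With a replicate block, a pairing by replicate number that the labels do not state, 1087 genes were called for rTIMP2 from day 7, 22 for day 7 against day 0, 0 for rTIMP2 in WT lungs and 2 for the interaction with tumour.

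Of the camera calls, 0 were kept with an estimated correlation in any of the 11 comparisons. Fry called 0 lists for rTIMP2 from day 0, 3 from day 7, 1 for day 7 against day 0, 29 for tumour in WT mice, 1 and 0 for MT2 against WT tumour-free and HBSS lungs, 16 and 3 for rTIMP2 in WT and MT2 lungs, and 0 for each interaction. Fry tests a list by itself and camera against the other genes.

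Leaving out 1 library at a time gave 861 to 1453 genes for rTIMP2 from day 0, 834 to 2149 from day 7 and 8 to 65 for day 7 against day 0. Tumour gave 11395 to 13018 in WT and 10879 to 12778 in MT2 mice. MT2 against WT gave 2 to 9 in tumour-free and 0 to 1 in HBSS lungs (1 without MT2 HBSS replicate 3 or 5). For rTIMP2 the range was 0 to 9584 in WT and 0 to 0 in MT2 lungs, and for the interactions 2 to 55 with tumour and 0 to 0 with rTIMP2. The libraries that moved a count by over 1.5 times are named with the comparisons.

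For the genes eligible to be named, 570 results gave 11367 values under alternatives, of which 9612 kept direction and side of the threshold, 1746 fell below it (1242 with 1 library left out), 8 passed it and 1 reversed. The reversed one was Timp2 for rTIMP2 from day 7, at -0.0027 (adjusted p = 0.99) without day 7 replicate 3, and its range with 1 library left out was -0.0027 to 0.07. The interaction of Timp2 with tumour, which had not passed, passed with sample weights (adjusted p = 0.00039) and without MT2 HBSS replicate 4 (0.013) or 5 (0.0077) or WT HBSS replicate 5 (0.041), or without the libraries high in squamous or muscle transcripts (0.021). Timp2 passed for rTIMP2 in WT lungs and for the interaction with rTIMP2 with sample weights (0.0024 and 0.0064).

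Simulated data took each gene's spread within groups, but drew the genes independently and changed few of them. There, 82% of changes by 2 times were found for rTIMP2 from day 0 and 82.5% for MT2 against WT tumour-free lungs, but 32.3% for rTIMP2 in WT lungs and 9.18% for the interaction with rTIMP2, where 46% of changes by 4 times were found. Variation that genes share between lungs, such as that along the tumour scale, was not simulated, so these shares may not carry over to the real lungs. Depth limits the genes near 10 counts and the reporter, whose values rest on few reads.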

Other observations

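The list members below come from the planned comparison of tumour with tumour-free lungs in WT mice. The values of Smim6 in tumour lungs and the ratio of Hmga2 to the reporter come from no planned test. All are given as further description.

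Several groups not described with the comparisons changed with intratracheal tumour in WT mice. Clock genes had 8 of 13 lower and 2 higher, with the repressor gene Nr1d1 at -3.11 and Cry1 at 1.52 ± 0.12 on the log2 scale. Of 18 immediate early genes 13 were lower, such as Btg2 (-3.07 ± 0.37) and Fos (-2.66). Checkpoint genes went both ways, with Cd276 (2.22 ± 0.15), Cd80 (1.30 ± 0.27) and Havcr2 (0.46 ± 0.18) higher and Cd274 (-0.86 ± 0.14), Vsir (-1.14 ± 0.21) and Ido1 (-2.22 ± 0.71) lower. Interferon gamma genes included rises of the chemokine genes Cxcl9 (2.73 ± 0.81) and Cxcl10 (2.72 ± 0.39) and of Socs1 (1.36 ± 0.17). Of 12 dendritic cell markers 10 were lower, while Fscn1 rose (3.48 ± 0.22). Neutrophil markers had 9 of 18 higher, such as Clec4d (3.54 ± 0.25), and Hdc, Retnlg and G0s2 (-3.87 ± 0.45) lower. The calls of Havcr2 and Retnlg were lost in at least 1 alternative.

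Smim6, the gene near Timp2 that was lower in tumour-free MT2 lungs, averaged 33.7 ± 67.3 (SD, n = 5, range 0 to 154) in MT2 and 77.5 ± 54.6 (17.1 to 149) in WT HBSS tumour lungs, ranges that overlap, since MT2 HBSS replicate 5 had 154 and the other 4 had 0 to 7.61. With rTIMP2 it averaged 24.6 ± 11.5 (8.83 to 37.4) in MT2 and 204 ± 67.4 (153 to 322) in WT tumour lungs.

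The ratio of Hmga2 to the reporter was 39.8 to 120 in WT and 43.5 to 88.9 in MT2 HBSS lungs of the intratracheal model, and 0.0323 to 0.655 in the subcutaneous lungs. The reporter values of the subcutaneous lungs thus came without the Hmga2 seen in intratracheal tumour lungs. What those reporter values stand for was not tested.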
